A study of Mus musculus with 2 samples.

How the data were processed

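H3K4me1 was measured by ChIP-seq in mouse forebrain at postnatal day 0, in 2 biological replicates of 1 group. Group and replicate number came from the labels. Fragments of 300 to 500 bp are given as the size range of both libraries, per the labels. The 4 deposited peak lists are 1 per replicate, 1 from the pooled alignments of both replicates and 1 replicated list, per the text notes deposited with the samples. The notes say that the replicated list was derived from the other 3 lists, without the rule. The aligner and the peak caller are not given in the sources used here. Coordinates are on mm10, per the labels. No list reached past the end of chromosome 1 of GRCm38 (195471971 bp).

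The deposited values of each peak are the fold enrichment, a ratio of ChIP over control, and −log10 p and −log10 q, all from the authors' peak caller. The deposited display score was not used. The deposited summit offset was used to place peaks in annotation classes. Fold, −log10 p and −log10 q were used to rank or filter peaks within a list, and median folds were compared only within a list, since neither depth nor scaling is known across lists. The prediction of X density cut the folds of each list against that list's own threshold. The permissive threshold of the deposited lists adds weak peaks: 32.4% of replicate 1's and 28.9% of replicate 2's peaks had a −log10 q of at least 2. Because peaks were called separately in each replicate, the number and width of a replicate's peaks move with its depth, which the lists do not give. Intervals on shares are 95% Wilson intervals. They cover counting error only, and neighbouring peaks are not independent.

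The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks were called shared when the overlap was at least 50% of either peak. For tests over positions, peaks were shifted 100 times along each chromosome after assembly gaps were removed, by at least 1000000 bp and circularly. Annotation was GENCODE M21, with 21728 protein-coding genes on the autosomes and X. Summits were assigned to promoter (1 kb either side of a TSS), exon, intron or intergenic sequence, in that order. Promoters were CpG-rich when 1000 bp of sequence around the TSS had an observed to expected CpG ratio of at least 0.6 and a GC content of at least 55%. TSS profiles ran to 5 kb either side in steps of 250 bp.

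Gene coverage was the number of base pairs in replicated peaks within 50 kb of the TSS. The 15 gene lists held 266 entries, all found in the annotation. Members within 100 kb of each other counted once. The lists shared some genes: Lhx6, Dlx1, Dlx6 and Arx, for example, were in those of forebrain patterning and of inhibitory neurons. Random lists were drawn 10000 times from genes in the same quintiles of length and of the number of TSSs within 50 kb. The p-values are permutations over genes and do not measure the spread between animals. Domains joined peaks up to 12.5 kb apart. The ratio between replicates used log2 of covered base pairs plus 1000 bp, in the strongest 95154 peaks of each.

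Genes were named by a rule fixed, like the tests, the gene lists and most alternatives, before the data were examined. It took for each list the counts above the 90th percentile and at 0 bp, the highest 2 members and the lowest; the 10 genes with most covered sequence; the genes of the 10 leading domains and of the 10 peaks of highest fold; the 5 genes with the largest ratio between replicates in each direction; and 21 fixed marker genes. Further genes in the lists were named to show members at 0 bp, after their values were seen.

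Overlap, coverage and profile functions were tested on simulated data, where 8000 intervals gave the same overlaps as bedtools 2.31.1. On 200 simulated lists of 20 genes with no change, set in 21000 genes whose coverage followed the matching classes, the gene list test called 5.0% at p under 0.05, against 36.0% without matching. With coverage raised 2.5-fold it called 63.0%, so that a list raised by less can be missed. Alternatives included other overlap rules, thresholds, windows, matching, the pooled list and each replicate alone. No comparison between groups was possible, since the series has 1 group.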

Results

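Histone H3 monomethylated at lysine 4 (H3K4me1), a chromatin mark of enhancers and of the flanks of active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse forebrain at postnatal day 0. The group held 2 biological replicates, both from healthy mice of the strain B6NTac;B6NCrl/Lap with males and females pooled, and the labels give both the same donor identifier. Replicate 1 came from the forebrains of 15 mice, and replicate 2 from a pool whose size the labels do not give. The data were 4 deposited peak lists on build mm10. Replicate 1 had 105915 peaks covering 34.1 Mb and replicate 2 had 95154 peaks covering 28.2 Mb, with median widths of 257 and 240 bp. Peaks called on both replicates' pooled alignments numbered 128889 and covered 50.2 Mb. The replicated list held 50678 peaks with a median width of 488.5 bp and covered 29.6 Mb, or 1.16% of the sequenced genome. The lists give no read numbers, so sequencing depth is unknown. Peaks with a −log10 q of at least 2 numbered 34285 in replicate 1, 27531 in replicate 2, 78600 in the pooled list and 46571 in the replicated list.

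Most replicated H3K4me1 peaks lay inside protein-coding genes, and promoters held the largest excess over chance positions. Summits lay in introns for 53.3% of the 50678 peaks (95% Wilson interval 52.9 to 53.8), in intergenic sequence for 28.0% (27.6 to 28.4), within 1 kb of a protein-coding transcription start site (TSS) for 13.0% (12.7 to 13.3) and in other exonic sequence for 5.65% (5.45 to 5.85). Against 100 circular shifts of the summits along each chromosome, promoter summits were 7.75-fold more frequent, exonic summits 1.596-fold and intronic summits 1.44-fold. Intergenic summits stood at 0.486 of the shifted mean. Each of the 4 classes lay outside all shifted values (two-sided permutation p = 0.0198, the smallest that 100 shifts allow). The split between promoter and gene body depended on the 1 kb limit. With promoters of 2 kb either side, 23.9% of summits were in promoters (7.25-fold) and 45.7% in introns (1.26-fold). Exons then held 3.69% (1.10-fold, two-sided permutation p = 0.0396). The shifts are over genome positions, so these p-values describe the lists and not the spread between animals.

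At promoters the peaks flanked the start site and were scarce on it. Of 21728 protein-coding TSSs, 3.69% (95% Wilson interval 3.45 to 3.95) were covered by a replicated peak at the TSS itself, 18.5% (17.98 to 19.01) at 1000 bp downstream and 10.3% (9.89 to 10.7) at 750 bp upstream. CpG-rich promoters, which are typical of broadly active and developmental genes, carried most of this shape. Among 8416 CpG-rich TSSs, 2.42% (2.12 to 2.77) were covered at the TSS and 34.1% (33.1 to 35.1) at 1250 bp downstream, against 19.3% (18.4 to 20.1) at 750 bp upstream. Among 13312 CpG-poor TSSs the share was 4.49% (4.15 to 4.86) at the TSS, and its downstream maximum was 9.56% (9.07 to 10.1). The ratio of the downstream maximum to the TSS was 14.1 in CpG-rich and 2.13 in CpG-poor promoters. With as many of the strongest peaks taken from replicate 2 or from replicate 1 alone, which cover less sequence, this ratio was 13.4 and 15.8 for CpG-rich promoters, while the downstream maximum was 19.7% and 23.7%.

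**Figure D1:**
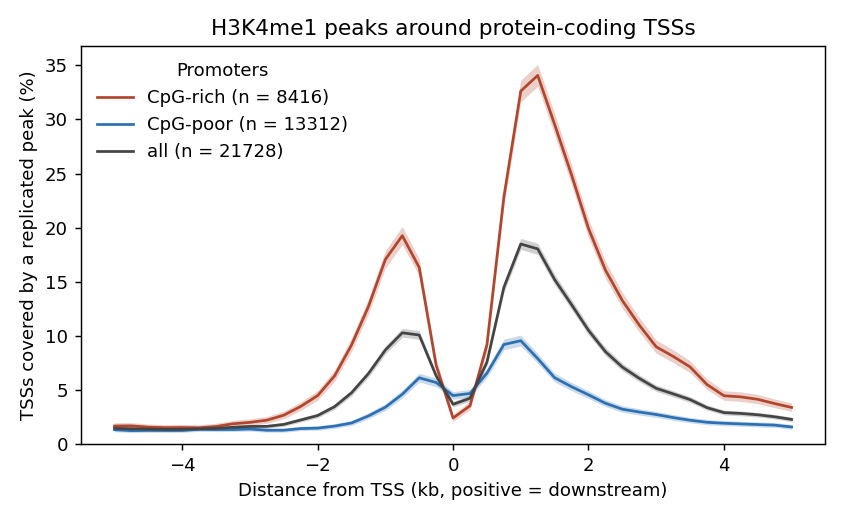
The share of protein-coding TSSs covered by a replicated H3K4me1 peak (y axis, %) is plotted against distance from the TSS (x axis, kb, positive downstream) for CpG-rich, CpG-poor and all promoters, with bands for 95% Wilson intervals. CpG-rich promoters fall to 2.42% at the TSS and reach 34.1% at 1250 bp downstream.

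The loci with the most H3K4me1 included genes of transcriptional regulators. The 10 protein-coding genes with the most covered sequence within 50 kb of the TSS, counting 1 gene per 100 kb, were Pipox (27874 bp), Ncor2 (25161 bp), Tcf20 (25099 bp), Thtpa (22857 bp), Foxo6 (21450 bp), Nr1d1 (21207 bp), Lrp8 (20591 bp), Zmynd8 (20481 bp), Bahcc1 (20300 bp) and Pcdhgc3 (19769 bp). The median over all genes was 1362 bp. Ncor2 encodes a nuclear receptor corepressor, Foxo6 a forkhead transcription factor, Nr1d1 a circadian nuclear receptor, Lrp8 a reelin receptor and Zmynd8 a chromatin reader. The windows of these genes were covered to a similar extent in each replicate's own strongest 95154 peaks, with 23113 and 21537 bp at Pipox and 20456 and 21151 bp at Ncor2 in replicates 1 and 2. This similarity follows in part from the choice of genes. They were picked on replicated peaks, of which 78.03% were overlapped by peaks of both replicates.

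Joining neighbouring peaks gave 23358 domains, of which 11199 held several peaks and 12159 were single peaks. Among all domains, 130 held at least 10 kb of peaks. The domain with the most, 54.1 kb in 63 peaks, spanned 187 kb of the gene Gse1 on chromosome 8 (120377899 to 120564879). It was followed by a domain over Tcf20 and Nfam1 on chromosome 15 (82897606 to 83043762, 39.4 kb of peaks) and by domains inside Pbx1, a homeodomain gene, on chromosome 1 (168268852 to 168395556, 34.5 kb) and inside Tcf4, which encodes a basic helix-loop-helix protein, on chromosome 18 (69496849 to 69614523, 31.3 kb). The next was a domain over Nfix and 6 neighbouring TSSs on chromosome 8 (29.5 kb), Nfix being a nuclear factor I gene of neural progenitors. The sixth lay in intergenic sequence on chromosome 2 (30646407 to 30744630, 29.3 kb), 51.4 kb from the nearest protein-coding TSS, that of Cstad. The remaining domains of the leading 10 lay in Ttc28 (29.1 kb), Map4k4 (23.6 kb), Pipox and Myo18a (23.2 kb) and Ncor2 (22.7 kb). The number of domains with at least 10 kb of peaks was 42 when peaks were joined only up to 5 kb, and 34 and 51 with the strongest 50678 peaks of replicate 2 and of replicate 1 alone. Of the leading 10 domains, 8 and 7 were also among the leading 10 in those replicates' peaks, but only 4 when peaks were joined up to 5 kb.

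Fold enrichment in the replicated list, as the authors' caller gave it for each peak, ranged from 1.63 to 8.25. The highest fold was at an intergenic peak on chromosome 8 (109464882 to 109465984), 28.8 kb from the TSS of Pmfbp1. The second highest (8.07) was intergenic on chromosome 11 (117408319 to 117410651), 75.6 kb from Gm11733. Of the other 8, 1 was intergenic, 72.4 kb from Lrrc74a, and 7 lay in introns. The intronic peaks were in Chd4, which encodes a nucleosome remodeller (fold 7.89, chromosome 6, 125097665 to 125100400), in Pdia6, in the histone demethylase gene Kdm4b, in Lrp8, in P4htm (nearest TSS that of Wdr6), in Vcp and in Trim62, with folds from 7.51 to 7.70 in the last 6. Those in Pdia6, Kdm4b, Vcp and Chd4 lay only 1.21 to 2.81 kb from the nearest TSS, and the other intronic peaks 8.41 to 27.6 kb.

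Genes of neurons and of radial glia and astrocytes were covered more than most matched random lists, as were broadly expressed genes, but none of 15 gene lists passed after adjustment. Each list's median covered sequence within 50 kb of the TSS was set against 10000 random lists matched on gene length and gene density (two-sided permutation p over genes, Benjamini-Hochberg over the 15 lists). For pan-neuronal and synaptic genes the median was 2911 bp, against 1370 bp in random lists (percentile 99.4, permutation p = 0.0124, adjusted p = 0.0900). Of its 22 members, 4 exceeded the 90th percentile of all genes (5521 bp) and 0 had no replicated peak. Dlg4 (13308 bp), the gene of the postsynaptic scaffold PSD-95, and Rbfox3 (9893 bp), the gene of the neuronal nuclear antigen NeuN, were the highest, and X-linked Syn1 (199 bp) the lowest. For radial glia and astrocyte genes the median was 2269 bp against 933.5 bp (percentile 99.1, permutation p = 0.0180, adjusted p = 0.0900). Notch1 (7205 bp) and Nes (5836 bp) led this list, and the astrocyte water channel gene Aqp4 had 0 bp. A value of 0 bp, found for 26.5% of all genes, means no replicated peak within 50 kb. Such a gene can still have peaks in a replicate's own list. For broadly expressed genes the median was 3863 bp against 1557 bp (percentile 99.6, permutation p = 0.00740, adjusted p = 0.0900), with Tuba1b (9500 bp) and Polr2a (7968 bp) highest and Pgk1, on chromosome X, lowest (364 bp). In all, 3 lists had an unadjusted permutation p under 0.05. In the pooled list, which is longer and less strictly selected, 5 lists passed: these 3, forebrain patterning and cortical projection neuron genes.

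Forebrain patterning genes, which encode the transcription factors that set up the telencephalon, had a median of 1386 bp against 655 bp in random lists (percentile 96.3, permutation p = 0.0750, adjusted p = 0.281). Emx1 (7166 bp) and Nr2f1 (4404 bp) were the highest of the 25, 1 exceeded the 90th percentile of all genes, and 4 had 0 bp (Dlx2, Lhx8, Nkx2-1 and X-linked Arx). Foxg1, the telencephalic forkhead gene, had 3983 bp (percentile 81.9 among all genes), Emx2 1819 bp, Pax6 1302 bp, Dlx1 1100 bp and Dlx5 531 bp. Among 20 cortical projection neuron genes 3 exceeded the 90th percentile. Neurod2 (14763 bp) and Bcl11b (12644 bp), both genes of transcription factors, were the highest, Satb2 had 1488 bp, Neurod6 1228 bp, Tbr1 877 bp and Mef2c 0 bp (list percentile 88.9, adjusted permutation p = 0.536). Inhibitory neuron genes were led by Zeb2 (8996 bp) and Cxcr4 (5372 bp), Lhx6 had 1983 bp, Gad1 1046 bp and Sst 0 bp (list percentile 82.2, adjusted permutation p = 0.536). The progenitor gene Sox2 had 726 bp. In unmatched lists forebrain patterning genes stood only at percentile 52.975 (1386 bp against 1346 bp), cortical projection neuron genes at 50.31, inhibitory neuron genes at 46.3, radial glia and astrocyte genes at 92.015 and pan-neuronal genes at 98.655. With GC content matched, a setting chosen after the data were seen that also used tertiles of length and density, forebrain patterning genes stood at percentile 95.41, cortical projection neuron genes at 92.675, inhibitory neuron genes at 67.17 and radial glia and astrocyte genes at 96.705, all within the central 95%, while pan-neuronal (99.835) and broadly expressed genes (99.70) passed (adjusted permutation p = 0.0465 each).

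Lists of other cell types lay within the central 95% of their random lists. Oligodendrocyte lineage genes stood at percentile 65.045, with Cnp (5447 bp) and Mbp (3231 bp) highest, Sox10 at 2771 bp, Olig2 at 2299 bp and Ugt8a at 0 bp. Microglia genes stood at percentile 52.1, with Aif1 (4400 bp) and Hexb (4173 bp) highest, Csf1r at 1374 bp and P2ry12 at 0 bp. Endothelial and mural genes stood at percentile 17.2, with Sox18 (5325 bp) highest, Cldn5 at 990 bp and Tek at 0 bp, and meninges and choroid plexus genes at 48.2, with Col1a1 highest (2379 bp). Erythroid genes stood at percentile 12.7, although Nfe2 (9836 bp) and Epor (7067 bp) were among 3 of 12 members above the 90th percentile. Gata1 and Alas2, both on X, had 0 bp, and without X genes the list's median rose from 838.5 to 2168.5 bp and its percentile to 65.8. Adjusted permutation p-values of these 5 lists ran from 0.536 to 0.966. With GC content matched as well, all 5 stood lower, at percentiles 23.48 (oligodendrocyte), 9.825 (microglia), 3.28 (endothelial and mural), 36.48 (meninges and choroid plexus) and 6.98 (erythroid), still within the central 95%.

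Genes of other regions and organs were in part covered as well. Midbrain, hindbrain and spinal cord genes stood at percentile 83.2 (adjusted permutation p = 0.536), but at 37.485 in unmatched lists and at 6.36 when GC content was matched as well, with Mnx1 (3414 bp) and Fev (3194 bp) highest, and 7 of 20 at 0 bp, among them En1, Hoxa9 and Phox2b. Liver genes stood at percentile 30.5, at 14.55 with tertiles of length and density alone, and at 7.26 with GC content matched alongside these tertiles. Of 17 liver genes 6 had 0 bp, including the albumin gene Alb, and Apoa2 (5515 bp) was highest. Muscle and heart genes stood at percentile 57.7 (4.10 with GC content matched), with the myogenic gene Myod1 (5654 bp) and Myh7 (4598 bp) highest, Nkx2-5 at 4270 bp and Myf5 at 0 bp. Germline and gut genes stood lowest, at percentile 5.42 (median 300 bp against 1181 bp, adjusted permutation p = 0.326), and with GC content matched at 1.065, below the central 95% (permutation p = 0.0216, adjusted p = 0.108), with Cdx1 (2202 bp) highest and 6 of 15 at 0 bp. For comparison, 26.5% of all genes had 0 bp. A 50 kb window can hold peaks of neighbouring genes, so covered sequence at a gene is not a measure of its activity.

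**Figure D2:**
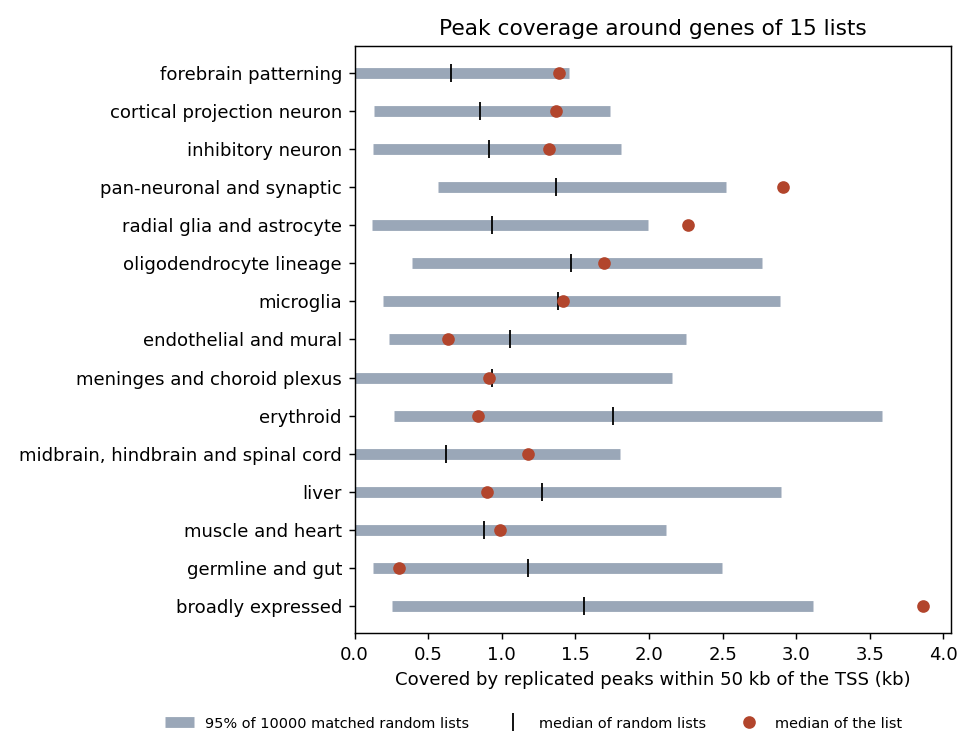
For each of 15 gene lists (y axis), the median sequence covered by replicated peaks within 50 kb of the TSS (x axis, kb) is shown as a red point, with the median (black tick) and the central 95% (grey bar) of 10000 matched random lists. Broadly expressed, pan-neuronal and radial glia and astrocyte genes lie right of their bars, at percentiles 99.6, 99.4 and 99.1.

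Each replicate's strongest peaks were overlapped by the other replicate's full list far more often than its weakest. The strongest peaks of both lists overlapped each other less often. Of replicate 1's peaks 33.3% (35217, 95% Wilson interval 33.0 to 33.5) were overlapped by a replicate 2 peak across at least 50% of either peak, and of replicate 2's peaks 38.1% (36282, 37.8 to 38.4). The shares were 21.8-fold and 22.3-fold those after circular shifts (one-sided permutation p = 0.00990 each, the smallest that 100 shifts allow). By strength within each list, the share overlapped by the other full list fell from 70.1% in the strongest decile to 16.8% in the weakest in replicate 1. In replicate 2 it fell from 72.2% to 21.8%. No shifts were run per decile, and peak width was not held fixed. When both lists were limited to the strongest 10000 peaks, 25.8% of replicate 1's were overlapped, against 35.1% at 95154 peaks. Covered base pairs had a Jaccard index of 21.2%, against 0.651% after shifts. Across 30661 peaks with a single partner, the ranks of fold enrichment had a Spearman's rho of 0.201. Peaks are not independent replicates, so no p-value is given for it.

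**Figure D3:**
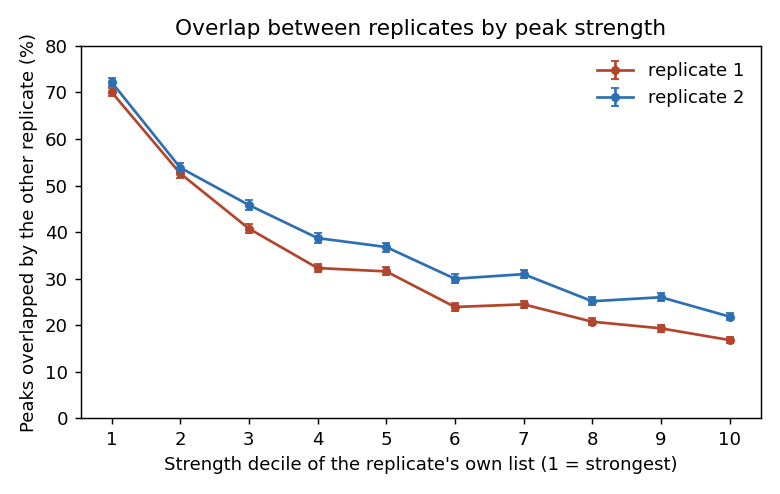
The share of each replicate's peaks overlapped by the other replicate's full list (y axis, %) is plotted against strength by −log10 p in deciles of the replicate's own list (x axis, 1 is strongest), with 95% Wilson intervals as bars. Replicate 1 runs from 70.1% to 16.8% and replicate 2 from 72.2% to 21.8%.

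All 50678 replicated peaks were identical to peaks of the pooled list, of which they made up 39.3%. Peaks of both replicates overlapped 39545 of them (78.03%), and all 39545 pooled peaks with that support were in the replicated list. The other 11133 had a partner in replicate 1 only (6224), in replicate 2 only (4617) or in neither (292), by a rule that the file notes do not state. These 11133 had a median fold of 3.19, against 3.57 for the 39545. When at least 50% of both peaks had to overlap, the share with support in both replicates was 37.1%.

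Among genes with at least 5000 bp covered in either replicate, coverage differed most around Itprid1 and Mtmr11, with more in replicate 1, and around Trappc3 and Mcam, with more in replicate 2. With 95154 peaks in each replicate and 1000 bp added to both values, the median log2 ratio of replicate 1 to replicate 2 over all genes was 0.02 (SD over genes 0.35). Those with the highest ratios were Itprid1 (1.26), Mtmr11 (1.25), Rufy3 (1.11), Cnr2 (1.11) and Reep1 (1.07), and the lowest were those of Trappc3 (-0.88), Mcam (-0.83), Igdcc3 (-0.76), the neurogenic gene Hes6 (-0.73) and Cd5 (-0.69). Lists of inhibitory neuron genes (median 0.27, percentile 99.1 of matched random lists) and forebrain patterning genes (0.21, percentile 98.2) lay above the central 95% of random lists, with more covered sequence in replicate 1, and so did radial glia and astrocyte genes (0.23, percentile 97.51). Midbrain, hindbrain and spinal cord genes lay just within it (0.21, percentile 97.3), as did the other 11 lists, with medians from -0.03 to 0.17. The 3 lists outside moved inside in some settings: forebrain patterning with a window of 100 kb, inhibitory neuron with that window or with 100 bp added, and radial glia and astrocyte genes in 4 of the 5 alternatives. Midbrain, hindbrain and spinal cord genes moved outside at 10 kb (percentile 98.985) and with 100 bp (97.56) or 5000 bp (98.42) added. They stayed inside at 100 kb (95.98) and with all peaks of each list (95.17). Equal numbers of peaks do not ensure equal covered sequence. In the full lists the median peak width was 257 bp in replicate 1 and 240 bp in replicate 2. The random lists were not matched on coverage, so a general excess in replicate 1 was not separated from a difference at these genes. The inhibitory neuron and forebrain patterning lists share Lhx6, Dlx1, Dlx6 and Arx, so their results are not independent. With 1 library on each side these percentiles describe the libraries only.

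Chromosome X carried very few H3K4me1 peaks. The replicated list had 118 peaks on X, or 0.722 per Mb, against 21.1 per Mb on the autosomes, so that X had 3.42% of the autosomal density (95% Poisson interval 2.83 to 4.10, covering counting error only). Autosomes ranged from 15.9 per Mb on chromosome 14 to 31.3 on chromosome 11. The density on X was 8.24% of the autosomal in replicate 1, 4.88% in replicate 2 and 6.28% in the pooled list. None of the lists had peaks on the Y chromosome or the mitochondrial genome. Of 948 protein-coding genes on X, 801 had no replicated peak within 50 kb (84.5%, against 23.8% of autosomal genes). The X-linked members of the gene lists, among them Arx, Gata1, Plp1 and Alas2 at 0 bp, were counted in the list medians. Without X genes, an alternative chosen after the data were seen, pan-neuronal and synaptic genes passed (percentile 99.99, adjusted permutation p = 0.00600). Over the 12 alternatives for that list the adjusted permutation p ranged from 0.00600 to 0.259.

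**Figure D4:**
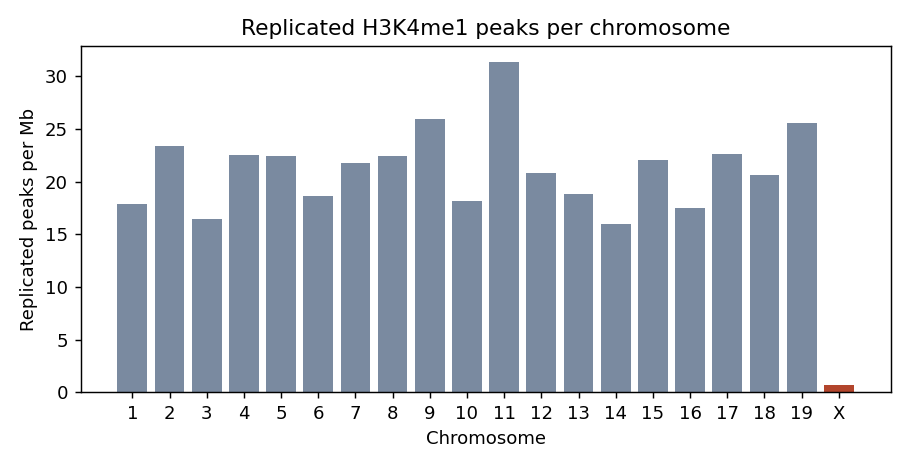
Bars give replicated H3K4me1 peaks per Mb of sequenced genome (y axis) for each chromosome (x axis), with X in red. X stands at 0.722 per Mb, and the lowest autosome, 14, at 15.9 per Mb.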

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

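The pooled list held 32029 peaks with a −log10 q of at least 2 that were not in the replicated list and so entered none of the main comparisons. They made up 24.9% of the pooled list. Of these peaks 14467 had a partner in replicate 1 only, 12248 in replicate 2 only, 5314 in neither and 0 in both, with a median fold of 3.0041 and a highest fold of 5.26.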

How the results depend on the processing

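Of the alternatives chosen before the data were examined, 198 held: tested results kept direction and side of the threshold, numbers of peaks and domains stayed within 1.5 times, other values moved by less than counting error, and ratios between replicates stayed on their side of the limits. The Jaccard index of covered base pairs was counted as held because it exceeded its values after all shifts. Further, 38 values moved, 14 list values went past a limit, 7 fell short of it and 14 changed direction. Of those chosen after the data were seen 52 held, 6 moved, 3 went past a limit and 9 changed direction. All 4 annotation classes kept direction and call under every alternative run, but the excess in exons fell to 1.10-fold with promoters of 2 kb either side. The cause of a difference was not tested unless stated. Depth is unknown, so its part in these differences is open.

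With a −log10 q of at least 2 the lists kept 78600 (pooled), 34285 (replicate 1) and 27531 (replicate 2) peaks, and with a fold of at least 3, 64512 (pooled) and 60713 (replicate 2), by construction of the stricter limit. Counting any overlap of 1 bp, the share of replicate 1's strongest peaks that were shared was 28.7% at 10000 peaks, 34.6% at 20000, 40.1% at 50000 and 43.6% at 95154. Ranking by fold gave 29.0% at 20000 and 33.0% at 50000. Rho of shared peaks was 0.287 when 50% of both peaks had to overlap. Replicated peaks with support in both replicates were 78.8% at 1 bp and 37.1% at 50% of both peaks.

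The pooled list, which covers more sequence, gave a share at the TSS of 6.04% over all promoters, 4.14% in CpG-rich and 7.25% in CpG-poor ones, with downstream maxima of 23.4%, 41.9% and 12.53%. Leaving out either replicate, which leaves as many but narrower peaks, gave 2.08 to 2.26%, 1.473 to 1.497% and 2.46 to 2.74% at the TSS, with maxima of 10.6 to 12.7%, 19.7 to 23.7% and 5.61 to 6.40%. Peaks found in both replicates' lists, a choice made after the data were seen, gave 3.06%, 1.94% and 3.76%, with maxima of 16.5%, 31.0% and 8.32%. Domains with at least 10 kb of peaks were 42 with joining up to 5 kb and 34 to 51 without a replicate. The density on X was 6.28% of the autosomal in the pooled list, 8.24% in replicate 1 and 4.88% in replicate 2.

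Among gene lists, the pooled list brought 5 past the limit: forebrain patterning (percentile 99.95, adjusted permutation p = 0.0165), cortical projection neuron (99.43, 0.0435), pan-neuronal and synaptic (99.90, 0.0165), radial glia and astrocyte (99.62, 0.0390) and broadly expressed genes (99.21, 0.0480). Pan-neuronal and synaptic genes also passed by number of peaks (99.93, adjusted permutation p = 0.0450), on autosomes only (99.99, 0.00600) and with GC content matched alongside tertiles of length and density (99.84, 0.0465). Broadly expressed genes passed in unmatched lists (99.91, adjusted permutation p = 0.0300) and in that GC setting (99.70, 0.0465). Tertiles without GC brought no list past the limit. The autosomal, GC and tertile settings were chosen after the data were seen. Over all 12 alternatives, adjusted permutation p ranged from 0.0165 to 0.994 for forebrain patterning, 0.0435 to 0.994 for cortical projection neuron, 0.00600 to 0.259 for pan-neuronal, 0.0390 to 0.733 for radial glia and 0.0300 to 0.233 for broadly expressed genes. With either replicate alone, no list passed. Lists that moved across the median of their random lists were past the limit neither before nor after. They were, by percentile, oligodendrocyte at 10 kb (7.35), with GC matched (23.48) and without replicate 1 (47.87, against 80.66 without replicate 2), microglia at 10 kb (10.985), by number of peaks (32.485), with GC matched (9.825), on autosomes (46.055), with peaks found in both replicates' lists (45.305) and without replicate 1 (46.615, against 70.64 without replicate 2), meninges by number of peaks (56.795), in the pooled list (52.195) and with tertiles (52.265), erythroid at 100 kb (63.47) and on autosomes (65.825), liver at 100 kb (56.195), midbrain, hindbrain and spinal cord unmatched (37.485) and with GC matched (6.36), muscle and heart unmatched (27.49), on autosomes (41.68) and with GC matched (4.10), and inhibitory neuron unmatched (46.3). Median ratios between replicates left the central 95% of random lists in 7 cases on the side where they lay, and in 2 on the other side (liver with all peaks, 0.395, and muscle and heart at 100 kb, -0.055), and entered it in 7, among them inhibitory neuron genes, which lay inside it at 100 kb (0.16) and with 100 bp added (0.37), and forebrain patterning genes at 100 kb (0.20).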

Other observations

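In this part, the test of GC bias on the promoter profile and the scaling of X dose by matched bins were chosen only after the results were seen, and the list of chromatin regulators was written after the leading loci were seen but before its own coverage was. A list of further chromatin regulator genes had a higher median coverage than matched random lists. Ncor2, Tcf20, Zmynd8, Bahcc1, Gse1, Chd4 and Kdm4b had been seen among the strongest loci, which gave the hypothesis that such genes carry more H3K4me1 than matched genes. A single list of 35 other chromatin regulators was then written without them. Its median was 4441 bp, against 2009 bp in 10000 random lists matched on GC content in quintiles and on gene length and density in tertiles (central 95% 1287 to 2899 bp). It lay above all of them (percentile 100, two-sided permutation p = 0.0002, the smallest these lists can give). Of the 35 genes 14 exceeded the 90th percentile of all genes, 1, Chd7, had 0 bp, and others such as Bcor (433 bp) and Sin3b (652 bp) lay below the median of all genes. Among the highest were the histone deacetylase gene Hdac5 (13721 bp), the remodeller gene Chd3 (13545 bp), the DNA methyltransferase gene Dnmt3a (13123 bp) and the Polycomb gene Cbx4 (13078 bp). The median was 3279 bp against 1316 bp with replicate 1's strongest peaks alone and 2363 bp against 1132 bp with replicate 2's. Broadly expressed genes also had a high percentile (99.6), and no expression data were used here, so the list's coverage may follow broad expression rather than the function of its genes. The random lists were not matched on the CpG class of promoters. Many genes of the list had CpG-rich promoters, among them Hdac5, Chd3 and Cbx4, though not Dnmt3a. Peaks covered up to 34.1% of CpG-rich TSSs downstream, against 9.56% of CpG-poor ones, so a part of promoter class in the list's coverage was not separated.

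Some recognition sequences of forebrain transcription factors ranked high in distal peaks among sequences of the same bases, by percentiles without adjustment for the number of sequences tried. In 22328 replicated peaks more than 10 kb from a TSS, the density of 7 sequences was compared with that in flanks of equal width 3 kb away, and the log2 ratio was ranked among all sequences with the same bases and the same number of CpGs. TTGGCA, bound by nuclear factor I proteins such as Nfix, was at 0.80 per kb in peaks and 0.55 in flanks (log2 ratio 0.56, percentile 100 of 119 sequences). TAATTA, bound by DLX and LHX homeodomain proteins, was at 0.36 and 0.33 per kb (0.15, percentile 100 of 13, whose median was -0.64). A first rank among only 13 sequences is weaker evidence than one among 119. CAGCTG, an E-box of ASCL1 and E-proteins such as Tcf4, had a log2 ratio of 0.73 and lay just past the limit of the 95th percentile, at 95.1. The highest of its 41 control sequences had 0.752. CAGATG, the E-box of NEUROD and NEUROG proteins, had 0.25 (percentile 87.4), which decides neither way. The SOX core ACAATG had -0.01 (percentile 74.7), the AP-1 site TGAGTCA -0.09 (percentile 53.0) and AGATAA, bound by the blood factors of the GATA family, -0.23 (percentile 62.1), all short of the hypothesis. The percentiles were not adjusted for the 7 sequences tried. A short sequence does not show which protein is bound.

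The pattern of few peaks on X was set against 3 technical explanations, and no biological one was tested because the design has 1 group. The sequence and gene content of X is argued against as the whole cause, since autosomal bins of 1 Mb matched to X on GC, repeats and gene density held 9.80 times the peaks per Mb of X. As a part of the cause it stays open, since these bins held 6.92 peaks per Mb against 21.1 in all autosomal bins. A lower dose of X in the ChIP libraries than in the control stays open, since X stood at 3.42% of the autosomal density, while a cut of all folds to 50%, at the 66.9% of autosomal gene density that X has, predicts 33.4% if only the pooled call must survive and 3.98% if the calls in all 3 lists must. These thresholds for what is still called were chosen after the prediction was written and after a first version of the test had been run on peaks found in both lists, and the predicted density depends on them. It also depends on the scaling: with the 32.8% of autosomal peak density that the matched bins had in place of gene density, the predictions are 16.4% and 1.955%, and the observed value lies between these. Survival in all 3 lists was taken only over autosomal peaks with a partner in both replicates' lists. Both replicates pooled males and females, so the loss of dose may be smaller than a cut to 50%. A smaller cut predicts more peaks on X, and none was run. Removal of X peaks regardless of strength also stays open: the median fold of X peaks in the pooled list was 2.82 against 3.0002 on autosomes, a difference of -6.13% (permutation p = 0.00650), between the limits of 5% and 10% set for it. In the replicates' own lists the median folds on X and autosomes were equal (3.1698 in replicate 1 and 3.2744 in replicate 2), values that 11.9% and 12.9% of their peaks share. A lower dose of X also predicts a lower median fold on X. The pooled list and the replicated list (3.34 against 3.54) had this, and the replicates' own lists did not.

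Peaks were concentrated in GC-rich sequence. Across 2403 autosomal bins of 1 Mb, Spearman's rho of peaks per Mb with GC content was 0.84, and the fifth of bins richest in GC held 46.3 peaks per Mb against 3.04 in the poorest. Gene density is argued against as the cause, since rho was 0.76 with gene density held fixed, while rho with gene density at fixed GC was -0.04. GC bias of the libraries stays open. As the whole cause it was not decided: at CpG-rich promoters the share covered at the TSS was 7.12% of its downstream maximum, but this gap was known beforehand and does not bear on bins of 1 Mb. As a part of the cause it fits its test: intergenic peaks more than 10 kb from a TSS exceeded their flanks by 3.77 percentage points of GC (median), as a bias predicts, and GC-rich enhancers could give the same difference.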
